A study of Drosophila melanogaster with 2 samples.

How the data were processed

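Small RNA was sequenced from heads of adult Canton-S females of Drosophila melanogaster, a laboratory wild-type strain, aged 3 to 5 days. One library came from flies kept in ethanol-free air for 45 minutes (control) and one from flies exposed to ethanol vapour for 15 minutes, until all were sedated, and then to ethanol-free air for 30 minutes (ethanol). Per the labels' protocols, each sample held about 180 flies, heads were separated from frozen bodies on sieves, RNA of 18 to 30 nt was cut from a gel, and libraries were made with an Illumina small RNA kit and sequenced on an Illumina HiSeq instrument. The labels give an RNA integrity number of 6.80 for the control RNA and 6.40 for the ethanol RNA. There is 1 library per group, so the difference between groups has no replicate check, and differences between libraries cannot be told from differences between treatments. A pool of many flies averages over individuals but is still a single sample.

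The authors deposited a count table for each library, with the number of reads assigned to each mature miRNA and to each candidate miRNA named by the authors. The genome build was BDGP5, per the submitters' processing notes; the aligner, the counting tool, the adapter trimming and the miRNA database release are not given in the sources used here. The deposited counts list only products with 5 or more reads, per the file contents, so an absent product has fewer than 5 reads or was not counted. Each library also has a total read number, 17337082 for the control and 17600983 for the ethanol library. The authors' second value per product is the RPM over that total. RPM recomputed from the counts differed from the deposited RPM by at most 4.9e-05. What the total counts (all, clean or mapped reads) is not given in the sources used here. A further pair of deposited tables compares the libraries and holds a log2 ratio, ethanol over control, of the RPM values and a p-value from the authors, whose test is not given in the sources used here. In the deposited table of candidates a count of 0 stands as 0.01 RPM before the log2 ratio, so those ratios are not measured folds.

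Mature products made by several hairpins can appear more than once, as did 6 names in each library. The largest count was kept for each name, as in the authors' comparison tables, and miR-276a-5p and miR-276b-5p, which are the same sequence with the same count, were used once. Both choices, and the matching of hairpin copies to the fixed lists, were made after the counts were seen. Counts were then scaled to CPM over all reads of known mature miRNAs, 13692046 in the control and 13128478 in the ethanol library. Products with at least 100 reads over both libraries were compared, which left 168 sequences of the 221 listed in both libraries. The 19 known sequences listed in only one library had at most 16 reads and were left out. Each ratio carries an exact conditional binomial (Clopper-Pearson) 95% interval, and each change in the ratio of a hairpin's arms an exact conditional 95% interval of the odds ratio. These intervals cover counting error only: reads made by PCR without molecular identifiers are not independent molecules, and variation between flies or between library preparations is outside them. No p-value was computed, because edgeR's and DESeq2's tests need replicates. Their scaling factors were used as alternatives (edgeR 4.0.16 TMM, DESeq2 1.42.0 size factors, R 4.3.3); all other steps used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and SciPy 1.17.1.

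A product was called higher or lower at a ratio of at least 2 or at most 0.5. The named products were the 12 highest and 12 lowest of these (all, as there were fewer), the 6 with the most reads, from each fixed list the member with the most reads and the one with the largest absolute log2 ratio (all members of lists of 3 hairpins or fewer), the 3 largest arm shifts each way and the 3 highest and 3 lowest candidates. The 16 lists, the thresholds and this rule were set before the data were examined. For lists with at least 3 compared products, the median log2 ratio was set against 10000 random lists of the same size drawn from the same 4 strata of mean expression; the percentile describes these 2 libraries and is no test of the treatment. Lists share members, and both arms of a hairpin count as separate products. The ratio steps were tested on simulated data: with 221 products drawn from the real means and library sizes, 55 of them changed, the intervals held the true ratio in 95.1% of cases at 100 reads or more, all products changed 4-fold either way passed the threshold, and no unchanged one did. The simulated counts held counting error only, with the true scaling supplied. They do not show how often unchanged products pass 2-fold between real libraries. Products given a 2-fold change, at the threshold itself, were not scored. The intervals of the arm ratio held the true value in 94.5% of cases. Of random lists drawn without any shift, 6.75% fell outside the middle 95%, and of lists with every member shifted 2-fold 99.75% lay above it. That shift is larger than any list median found here, so the share does not show how often smaller shifts would be seen.

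The alternatives were TMM and DESeq2 scaling, the total without the 10 most abundant products, the authors' RPM, read minimums of 10, 1000 and none, a 1.5-fold threshold, a threshold on the interval instead of the ratio, and summing the products of a hairpin. A correction for guanine content, summing of repeated rows, use of the more abundant arm alone, and the arm ratio with mir-276a left out or summed with mir-276b were added after seeing the data, as were the relation to guanine content and the pairing of candidates by overlapping sequence (one sequence, less up to 2 bases at its ends, within the other). The guanine correction removed a straight-line fit, centred on the mean guanine content of the compared products, without rescaling to the read total. Levels and signs of products and lists after it depend on that centring. The reference gene table is of the assembly Release 6 plus ISO1 MT, not BDGP5, so no coordinates are printed. It was used only for which miRNA genes neighbour each other, and 101 hairpins were matched to it by name and 6 were not.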

Results

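The study profiled microRNAs, small RNAs that lower the output of messenger RNAs with matching sites, in female fly heads after a single sedating exposure to ethanol vapour. The control library held 17337082 reads, of which 13692046 (78.98%, exact 95% interval 78.96 to 78.99%) were assigned to 233 known mature sequences. The ethanol library held 17600983 reads, of which 13128478 (74.59%, 74.57 to 74.61%) were assigned to 228. The 4 most abundant products took 79.5% of the miRNA reads in the control and 77.7% in the ethanol library. The values below are CPM of known miRNA reads or ratios of them, ethanol over control, from 1 library per group. All intervals are 95% and cover counting error only.

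The same 6 miRNAs had the most reads in both libraries, each within 2-fold, with miR-1-3p first in the control and miR-184-3p first in the ethanol library. miR-1-3p, the muscle miRNA, made up 31.3% of control and 30.1% of ethanol miRNA reads. miR-184-3p made up 25.6% and 31.4%, a ratio of 1.23. let-7-5p, a regulator of developmental timing that is kept in the adult brain, made up 12.4% and 8.14% (1.52-fold lower), and miR-34-5p, linked to brain ageing, 10.3% and 8.06% (1.28-fold lower). After the correction for guanine content the log2 ratio of miR-184-3p was 0.68 (0.30 before), that of let-7-5p -0.29 (-0.60 before) and that of miR-34-5p 0.14 (-0.35 before). These products and miR-1-3p all rose under the correction, which was not rescaled to the read total. The sign of a corrected value therefore depends on where the correction was centred. miR-276a-3p, which acts in memory circuits, made up 2.78% and 5.08%, a ratio of 1.83 (1.82 to 1.835). miR-33-5p, which lies in the gene of the lipid regulator SREBP, was 1.15-fold lower, a log2 ratio of -0.20 that was -0.10 after the same correction. miR-276b-3p, a near-identical relative of miR-276a-3p named here after its value was seen, had a ratio of 1.74 (1.72 to 1.77), and reads of the pair could be split between them by the counting.

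The comparison of ethanol with control asked which miRNA levels differ after the exposure. Of 168 products, 4 were at least 2-fold higher in the ethanol library, 2 were at least 2-fold lower, and 162 (96.4%) lay within 2-fold. The higher ones were miR-304-5p, with 47 and 141 reads in control and ethanol (ratio 3.13, 2.23 to 4.45), miR-1008-3p with 29 and 71 reads (2.55, 1.64 to 4.08), miR-1003-3p with 1105 and 2649 reads (2.50, 2.33 to 2.68) and miR-193-3p with 10604 and 22782 reads (2.24, 2.19 to 2.29). After the correction for guanine content, miR-193-3p had a log2 ratio of 0.92 (1.16 before) and miR-1003-3p of 0.87 (1.32 before), both higher but under the threshold, and miR-304-5p and miR-1008-3p stayed past it. miR-1003 and miR-1008 are mirtrons, which are cut from spliced introns instead of by Drosha. The lower ones were miR-308-3p, with 697 and 46 reads (14.5-fold lower, 10.8 to 20.03), and miR-11-5p with 91 and 35 reads (2.49-fold lower, 1.67 to 3.79). miR-308-3p belongs to the K-box family, which shares a seed with miR-2, and miR-11-5p is the rarer arm of another K-box hairpin. Just inside the threshold, miR-277-5p was 1.98-fold lower (1.94 to 2.03) and miR-124-3p, the abundant neuronal miRNA, 1.93-fold lower (1.91 to 1.95). Under the authors' RPM both passed it, so that 4 products were lower.

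Across the 168 products the 2 libraries correlated with Pearson's r = 0.988 and Spearman's rho = 0.983 on log2 CPM; this is across miRNAs, which are not replicates. The median log2 ratio was -0.020, with quartiles of -0.28 and 0.32. The counting interval excluded a ratio of 1 for 62 products on the high side and 64 on the low side, and held 1 for 42, so at this depth counting error is small beside the differences between libraries. How far 2 libraries of the same treatment would differ was not measured.

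**Figure D1:**
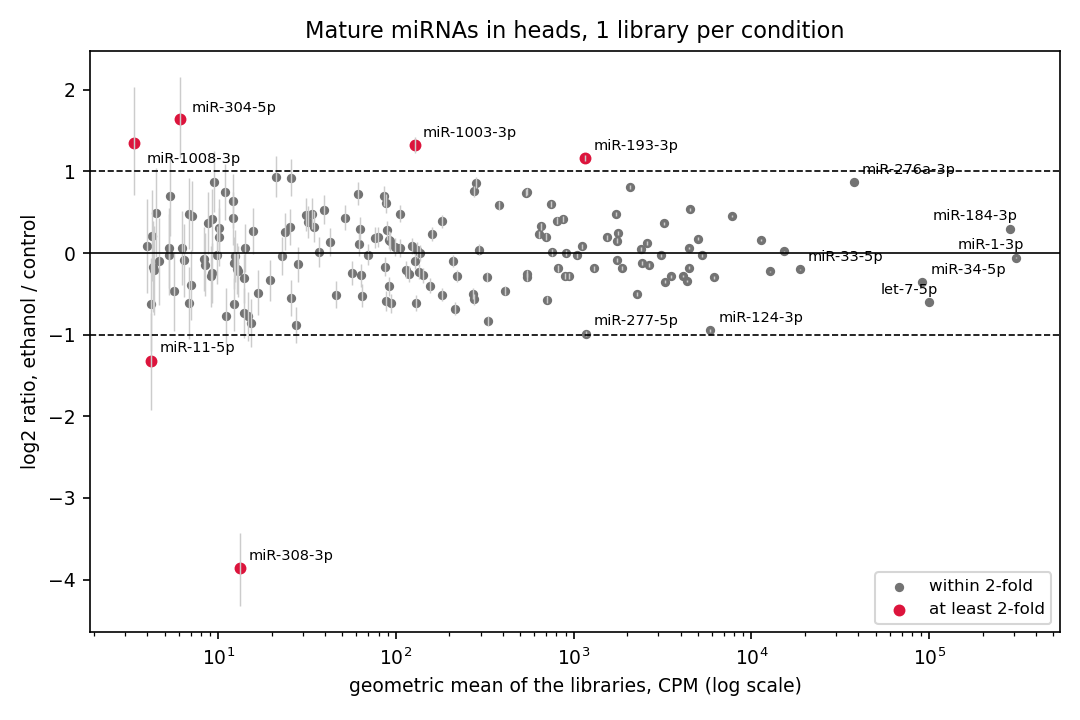
Log2 ratio of ethanol over control CPM (vertical axis) against the geometric mean CPM of the 2 libraries (horizontal axis, log scale) for 168 mature miRNAs; grey bars are 95% counting intervals and dashed lines mark 2-fold. 6 products (red) lie outside the lines, with miR-308-3p at -3.86.

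The log2 ratio was lower for products with more guanine in the mature sequence. Over the 168 products Spearman's rho was -0.50 and Pearson's r -0.38, against rho of 0.22 for cytosine, 0.19 for uracil and 0.056 for adenine, the 4 bases of the sequence. The 42 products lowest in guanine had a median log2 ratio of 0.30, with 33 above 0, and the 42 highest had -0.26, with 9 above 0. The relation was seen in products with 10000 reads or more (rho -0.40, 58 products) and within 5p (-0.42) and 3p products (-0.48). By part of the sequence, rho was -0.30 for guanine in the first 7 bases, -0.47 for the bases between and -0.088 for the last 7. These values are across miRNAs, which are not independent replicates, in 1 pair of libraries. The relation was found after the ratios were seen, among many sequence features looked at.

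**Figure D2:**
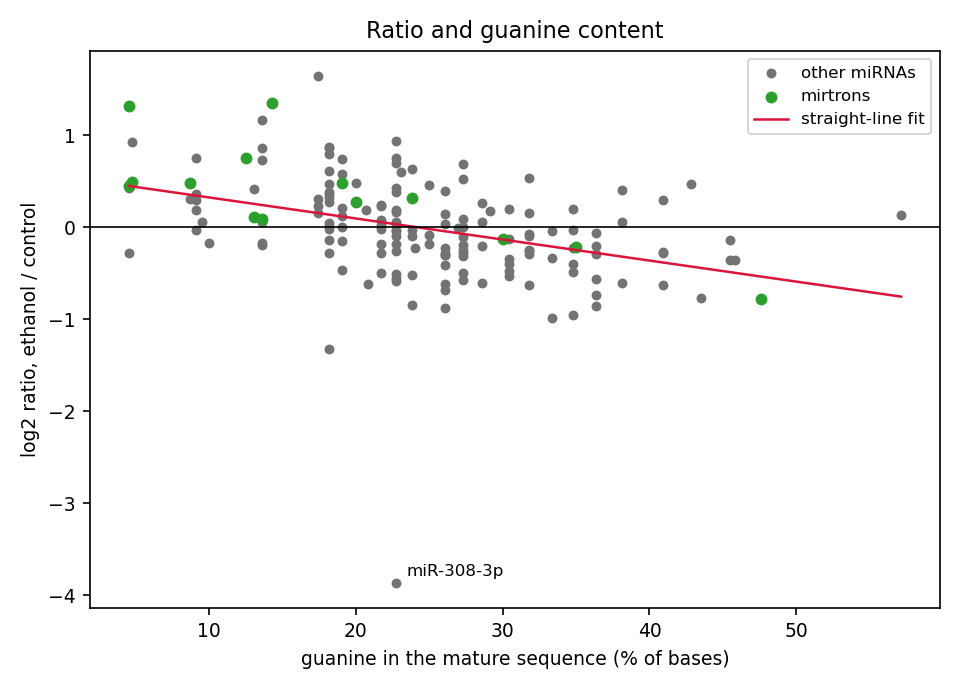
Log2 ratio of ethanol over control (vertical axis) against the percent of guanine in the mature sequence (horizontal axis) for 168 miRNAs, with mirtron products in green and a straight-line fit in red. The slope is -0.23 on the log2 scale per 10 percentage points of guanine, and miR-308-3p lies far below the line.

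Mirtron products were higher in the ethanol library as a group. Of 14 compared products, 11 had a ratio above 1, with the counting interval above 1 for 7 and below 1 for 1. Over all 168 products the interval lay above 1 for 62 and below 1 for 64. The median log2 ratio was 0.39, at percentile 99.2 of random lists matched on expression and 97.8 of lists matched on guanine content in 4 strata (88.4 in 12 strata). miR-1010-3p, the most abundant of them, had 2883 and 4663 reads (ratio 1.69, 1.61 to 1.77), and miR-1008-3p had the largest ratio. All 10 compared 3p products lay above 1, with a median of 0.48, while 3 of the 4 compared 5p products lay below 1, with a median of -0.17. The 3p products held a median of 12.8% guanine and the 5p products 32.5%. After the correction for guanine content the list's median was 0.083.

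Lists tied to the nervous system held products with ratios on both sides of 1. In the nervous system list 6 of 14 products were above 1 and 8 below, with a median of -0.17 (percentile 14.6) that became 0.054 when the more abundant arm alone was used. miR-34-5p and miR-124-3p were lower, as given above; miR-124-5p, named after its value was seen, was 1.84-fold lower (1.58 to 2.14), like the other arm of its hairpin. The retina and sense organ list had 8 of 12 products above 1 and a median of 0.062 (percentile 67.2), which was -0.020 under the authors' RPM. In it, miR-263a-5p, which protects sense organ cells, had a ratio of 1.37 (1.36 to 1.39), and miR-1000-3p was 1.81-fold lower (1.48 to 2.23). The more abundant arm of that hairpin, miR-1000-5p, named after its value was seen, went the other way. It had 5720 and 9164 reads (1.67, 1.62 to 1.73). Among relatives of miRNAs linked to ethanol in mammals (miR-7, the miR-9 and miR-79 group, miR-124 and let-7), 7 of 12 products were above 1, with a median of 0.21 (percentile 90.6) that was -0.19 for the more abundant arms alone. Its most abundant member, let-7-5p, and the one farthest from 1, miR-124-3p, were both lower. No product of these 3 lists reached 2-fold in CPM.

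The medians of the clock-linked and apoptosis-linked miRNAs lay below those of most random lists. In the clock-linked list 10 of 15 products were below 1 and the median was -0.27 (percentile 1.93), with let-7-5p the most abundant member and miR-124-3p the one farthest from 1. The median was -0.10 for the more abundant arms alone and -0.030 with a minimum of 10 reads. In the apoptosis-linked list 13 of 20 products were below 1 and the median was -0.26 (percentile 1.51), but for the more abundant arms alone it was 0.26. Among lists matched on guanine content the percentiles were 3.89 and 0.885. Percentiles were computed for 10 lists. Its most abundant member was miR-263a-5p and the one farthest from 1 was miR-11-5p. The K-box family, in part the same miRNAs, had 10 of 15 products below 1 and a median of -0.23 (percentile 5.49), against 0.28 for the more abundant arms. Its most abundant product, miR-2a-3p, had a ratio of 1.19 (1.17 to 1.21), while miR-308-3p was the lowest of all. The miR-959 to miR-964 cluster was near the listing limit, and its only compared product, miR-964-5p, had 66 and 59 reads (0.93, 0.64 to 1.35).

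The let-7 complex, 3 miRNAs from a single transcript, had 3 products above 1 and 3 below, with a median of -0.12 (percentile 28.5). let-7-5p had a ratio of 0.66 and let-7-3p of 1.66. miR-125-5p had a ratio of 1.39 and miR-125-3p of 0.73. miR-100-5p had a ratio of 1.01 (0.89 to 1.15) and miR-100-3p of 0.84. The metabolism and fat body list had 8 of 12 products below 1 and a median of -0.19 (percentile 8.31), led by miR-33-5p in abundance and by miR-277-5p, whose hairpin regulates branched-chain amino acid breakdown, in distance from 1. Its median was -0.088 after the correction for guanine content. miR-277-3p, the more abundant arm of the mir-277 hairpin and named after its value was seen, had 22783 and 24268 reads (1.11, 1.09 to 1.13).

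miRNAs listed beforehand as markers of tissues that a sieved head sample could carry had ratios between 0.76 and 1.62 where they had at least 100 reads over both libraries. Among those with fewer, the counting interval excluded 1 for miR-6-3p of the early embryo cluster (10 and 37 reads, ratio 3.86, 1.88 to 8.70) and for miR-310-3p (8 and 25 reads, 3.26, 1.43 to 8.36) and miR-313-5p (31 and 13 reads, 0.44, 0.21 to 0.86) of the gonad cluster, all 3 named after their values were seen. miR-1-3p of muscle had a ratio of 0.96, and a log2 ratio of 0.22 after the correction for guanine content. The gut miRNA miR-281 had ratios of 1.06 (0.99 to 1.14) for miR-281-2-5p, 0.95 (0.73 to 1.25) for miR-281-1-5p and 0.99 (0.70 to 1.39) for miR-281-3p. The list labelled posterior Hox also held miR-10, which is not a posterior marker. In it, miR-10-3p had a ratio of 0.81 (0.80 to 0.82) and miR-10-5p of 0.99 (0.90 to 1.08), and miR-iab-4-5p had 14 and 12 reads. In the early embryo cluster miR-5-5p had 2445 and 1779 reads (0.76, 0.71 to 0.81). In the gonad cluster miR-312-3p had 58 and 90 reads (1.62, 1.15 to 2.29), and in the testis clusters miR-982-5p had a ratio of 1.24 (0.97 to 1.58). The gonad cluster summed to 105 and 150 reads and the testis clusters to 187 and 192. All flies were female, so the testis clusters cannot mark testis here. Which tissue the reads of these lists came from was not tested.

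**Figure D3:**
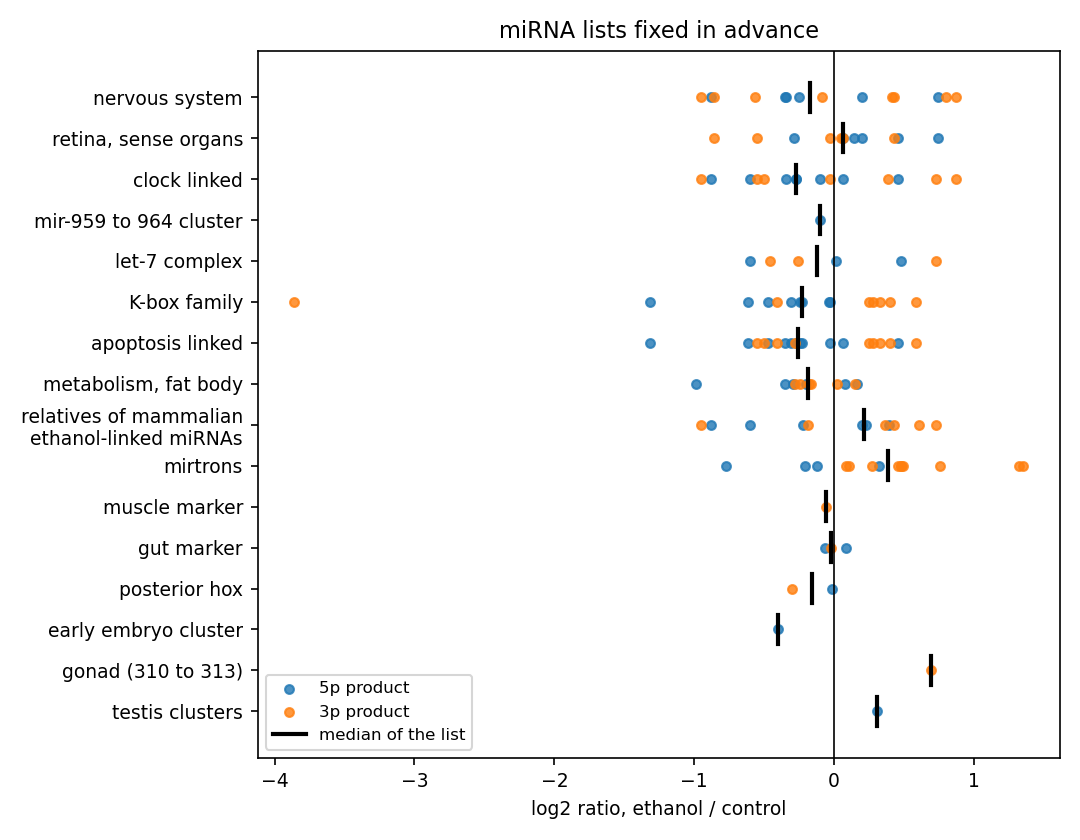
Log2 ratio of ethanol over control (horizontal axis) for each compared product of the fixed miRNA lists (rows); blue points are 5p and orange points 3p products, and black bars are list medians. The mirtron median lies at 0.39, with all 10 of its 3p products above 0.

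The ratio between the products of a hairpin's arms does not depend on the scaling between libraries. For mir-276a the 5p reads are shared with mir-276b, which has the same 5p sequence. Of 61 hairpins with both arms compared, 30 had arms on opposite sides of 1, and the log2 ratios of the more and the less abundant arm had Pearson's r = -0.052 and Spearman's rho = -0.029, across hairpins, which are not replicates. The arm ratio differed at least 2-fold in 11 hairpins (6 after the correction for guanine content), in 7 towards the 3p arm and in 4 towards the 5p arm. One of the 11 was mir-276a (odds fold 2.32, 2.29 to 2.35), and with the 3p reads of mir-276a and mir-276b summed against their shared 5p sequence the odds fold was 2.31 (2.28 to 2.34); mir-276a is named after its value was seen. The largest shifts towards 3p were in mir-1003, whose 3p share was 80.8% in the control and 94.7% in the ethanol library (odds fold 4.27, 3.43 to 5.33), mir-11 (3.74, 2.50 to 5.71) and let-7 (2.51, 2.28 to 2.78). The largest towards 5p were in mir-308, whose 3p share was 68.8% and 13.5% (14.1-fold lower odds, 10.01 to 20.3), mir-1000 (3.03-fold lower, 2.47 to 3.73) and mir-316 (2.05-fold lower, 1.61 to 2.62). miR-308-5p itself had 316 and 295 reads, a ratio of 0.97 (0.83 to 1.14). The shift was larger towards the arm with less guanine (Spearman's rho = -0.59 over 61 hairpins).

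**Figure D4:**
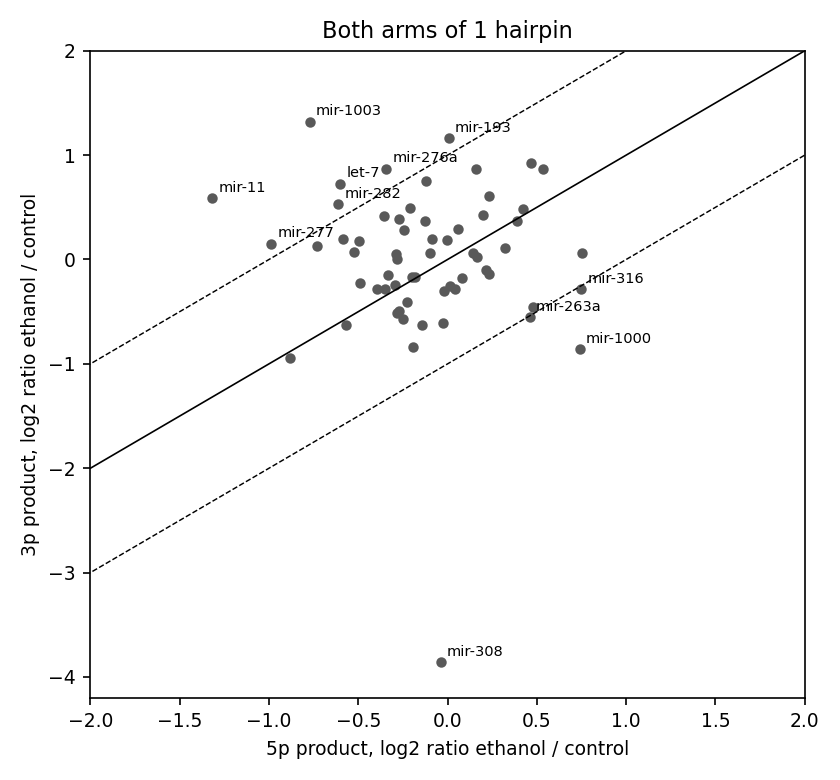
Log2 ratio of ethanol over control for the 3p product (vertical axis) against the 5p product (horizontal axis) of 61 hairpins; the solid line marks equal ratios and the dashed lines a 2-fold shift between arms. 11 hairpins lie outside the dashed lines, mir-308 farthest.

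Candidate miRNAs named by the authors were rare in both libraries. Their sequences were not matched here to other RNA classes such as tRNA fragments. The control listed 65 candidates with 1651 reads and the ethanol library 63 with 1621. Of 99 candidates in all, 29 were listed in both libraries, 36 in the control and 34 in the ethanol library alone. Among those in both, 3 had at least 100 reads and none of the 3 differed 2-fold. novel_mir_38 had 47 and 53 reads (1.18, 0.78 to 1.78), novel_mir_18 had 346 and 355 (1.07, 0.92 to 1.24) and novel_mir_53 had 111 and 108 (1.01, 0.77 to 1.33). In 7 pairs, a candidate listed in the control alone and one listed in the ethanol library alone overlapped so that one of the sequences, less up to 2 bases at its ends, lay within the other. In one of them, novel_mir_62 (TTGGGGGGCGCGGGTGGTGGC) had 24 control reads and novel_mir_97 (TTGGGGGGCGCGGGTGGTGG) 24 ethanol reads.

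The authors' deposited table of known miRNAs marks 14 of 196 products as different, 7 higher and 7 lower in the ethanol library. All 14 have a log2 ratio beyond 1 either way and a p-value of at most 0.00567 in that table. 8 of them had at least 100 reads and were compared here, and 6 of these were the products named above as 2-fold higher or lower. The other 2, miR-124-3p and miR-277-5p, passed 2-fold in RPM but not in CPM. The remaining 6 in the authors' deposited table rest on fewer reads over both libraries, down to 24. The authors' deposited table of candidates marks 13 of 26, of which 12 have a count of 0 in one library. The other is novel_mir_29, with 42 and 21 reads and a log2 ratio of -1.02 in that table. P-values in the authors' deposited tables compare the 2 libraries, not the treatments.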

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

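All tests in this part were chosen after the results were seen, except the comparison of the mirtrons with random lists matched on guanine content in 4 strata and the search for sequences similar to miR-308-3p; the repeat with 6, 8 and 12 strata was added after the 4-strata value was seen.

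Of the candidate miRNAs, which the comparison of known miRNAs does not use, 5 had reads in the ethanol library and are listed at 0 in the control in the authors' deposited table: novel_mir_89 with 341 reads, novel_mir_81 and novel_mir_95 with 48 each, novel_mir_79 with 32 and novel_mir_97 with 24. The reverse was also seen: the authors' deposited table lists 7 candidates at 0 in the ethanol library, and of these novel_mir_24 had 18.1 RPM in the control, against 19.4 RPM for novel_mir_89 in the ethanol library. The 7 include novel_mir_62, with 24 control reads, whose sequence is that of novel_mir_97 with 1 more base at the end, so for this pair the 0 in each library goes with the naming of the ends. Whether these sequences are fragments of other RNA classes was not analysed here.

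The ratio of ethanol to control was lower for products with more guanine, a relation found on these data after looking at arm, end bases, length, GC content, abundance, each base, segments and dinucleotides. Counting error is argued against by rho = -0.40 among the products with 10000 reads or more, and a difference in the supply of hairpins alone by rho = -0.59 between the arm shift and the arms' difference in guanine, since the arms share a precursor, apart from the 5p reads of mir-276a. A loss of guanine-rich reads of every kind was not decided: the 29 candidates in both libraries, with a median of 50.0% guanine, had a median log2 ratio of 0.061 (bootstrap interval -0.13 to 0.28) where the miRNA trend gives -0.59, but 26 of them had fewer than 100 reads. Sequence-dependent recovery in the making of 1 library may be the source, and with 1 library per group it cannot be told apart from an effect of ethanol on mature miRNAs, which was not tested.

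Mirtron products were higher in the ethanol library as a list. Counting error alone is argued against by 7 of 14 products with a counting interval above 1. The interval also lay above 1 for 62 of all 168 products. Such intervals are common at this depth, so the count does not set the mirtrons apart. Guanine content of the products stays open: with 4 strata the percentile was 97.8, just past the edge of the middle 95% of random lists, which by the bound set beforehand would have argued against it, but that bound took no account of how coarse the strata are, and the repeat with 4, 6, 8 and 12 strata gave 97.9, 93.3, 95.8 and 88.4, while the linear correction lowered the median from 0.39 to 0.083. A greater supply of the hairpins alone was not decided for the list. The counting intervals of the arms parted in 2 of the 4 hairpins with both arms compared and overlapped in the others. Supply alone would not part them: miR-1003-5p had a ratio of 0.59 (0.47 to 0.72) and miR-1003-3p of 2.50 (2.33 to 2.68). An effect of ethanol on mirtrons was not tested apart from these.

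miR-308-3p was 14.5-fold lower in the ethanol library. Lower supply of the hairpin is argued against by the 5p arm, at 0.974 of the control, and scaling between libraries by the odds of 3p against 5p, at 0.0707 of the control. Reads shared with a similar miRNA are argued against by the closest other listed sequence being 7 edits away. The guanine trend, at -0.23 on the log2 scale per 10 percentage points, is too shallow to give a ratio this low. The corrected log2 ratio of -3.90 was therefore bound to stay far from 0 and is no separate test of guanine content. Loss in the making of 1 library stays open with 1 library per group and cannot be told apart from an effect of ethanol on this strand, which was not tested.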

How the results depend on the processing

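No paired analysis was possible because each group has 1 library, and no library could be left out. The 4 scalings moved every log2 ratio by between -0.082 (the authors' RPM) and 0.057 (total without the 10 most abundant). The correction for guanine content, the sum of repeated rows the more abundant arm alone and the settings for mir-276a were chosen after seeing the data, all other alternatives before. The count of products at least 2-fold higher, 4, was 7 with a read minimum of 10 or none, 2 with 1000, 2 after the guanine correction (miR-193-3p and miR-1003-3p then had log2 ratios of 0.92 and 0.87) and 21 at 1.5-fold; it stayed between 3 and 5 under the other settings run. The count at least 2-fold lower, 2, was 4 under the authors' RPM, 5 with a minimum of 10 or none, 0 with 1000, 1 with hairpin products summed, 18 at 1.5-fold and 1 when the whole interval had to pass 2-fold (2 or 3 under the other settings); miR-308-3p and miR-11-5p have fewer than 1000 reads. The median over all products, -0.020, was 0.037 without the 10 most abundant in the total, -0.10 under the authors' RPM, 0.062 with hairpin products summed and 0.014 with a minimum of 10 or none. The number of hairpins with a 2-fold arm shift, 11, was 5 with a minimum of 1000 and 6 after the guanine correction (11 with mir-276b's 3p reads added to those of mir-276a, 10 without mir-276a). With a minimum of 10, 2 candidates differed 2-fold (novel_mir_19 and novel_mir_28), and both intervals held 1. The interval of novel_mir_29, named after its value was seen, excluded 1 without passing 2-fold in CPM (42 and 21 reads, 0.52, 0.29 to 0.90). Among list medians, 18 of 100 alternative values had the other sign, 6 of them for lists within 0.1 of 0 (the gut list, 5 values from 0.036 to 0.10, and the retina list, -0.020 under the authors' RPM). The other 12 took the nervous system list to 0.20 (minimum 1000), 0.031 (hairpins summed), 0.029 (guanine correction) and 0.054 (more abundant arm); the K-box family to 0.25 (minimum 1000), 0.23 (hairpins summed) and 0.28 (more abundant arm); the apoptosis list to 0.19 (hairpins summed) and 0.26 (more abundant arm); and the relatives of mammalian ethanol-linked miRNAs to -0.12 (hairpins summed), -0.0028 (guanine correction) and -0.19 (more abundant arm). Signs of single products were checked for 15 of those named: the 6 past 2-fold, the 6 with the most reads, miR-124-3p, miR-277-5p and miR-276b-3p. Of these, miR-34-5p had the other sign after the guanine correction, at 0.14. So did miR-1-3p after it and without the 10 most abundant, at 0.22 and 0.0008. The other named products were not checked in this way, and miR-100-5p, just above 1 in CPM, had a log2 ratio of -0.068 in the authors' deposited RPM. Signs after the guanine correction depend on its centring, which was not rescaled to the read total. Summing hairpins and using 1 arm drop the rarer arm's weight by construction; for the other sign changes the cause was not tested. Depth limits the products below 100 reads most, where the smallest listed count is 5.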

Other observations

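The products named here were chosen after their values were seen, except where the rule for named products covers them; the test of neighbouring genes was chosen before its result was seen. miRNAs of the cluster of mir-283, mir-304 and mir-12, which neighbour each other in the annotation, had the largest differences among the neighbour pairs: miR-304-5p had a ratio of 3.13, miR-283-5p of 0.98 (0.77 to 1.26), and miR-12-5p was 1.60-fold lower (1.52 to 1.69). miR-92b-3p, with 209 and 383 reads, had a ratio of 1.91 (1.61 to 2.27), and the products of its neighbour mir-92a lay on both sides of 1, miR-92a-3p at 1.31 (1.14 to 1.496) and miR-92a-5p at 0.83 (0.75 to 0.91). Other neighbour pairs were mixed. miR-275-3p and miR-305-3p had log2 ratios of -0.23 and -0.18, and miR-279-3p and miR-996-3p of -0.030 and 0.052, whereas miR-998-5p and miR-11-3p had -0.28 and 0.59, miR-100-3p and miR-125-5p -0.26 and 0.48, and miR-277-3p and miR-34-5p 0.15 and -0.35. These pairs took the product with the most reads of each hairpin, and the discordant ones set a 5p against a 3p product. Products of the same arm shared a sign in those pairs, though not always a size. miR-998-5p and miR-11-5p had -0.28 and -1.32, miR-100-3p and miR-125-3p -0.26 and -0.46, and miR-277-3p and miR-34-3p 0.15 and 0.41. In the early embryo cluster miR-5-5p had 2445 control reads, miR-3-3p 8 and miR-286-3p 21.

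One hypothesis was that miRNA genes close together have similar ratios because they share a primary transcript. Over 18 pairs of neighbours within 10 kb, the median absolute difference of log2 ratios was 0.29, against 0.45 when values were shuffled among 101 hairpins, at percentile 7.02 of the shuffled values. That lies above the bound set beforehand, the 5th percentile, so a shared transcript may contribute but was not decided by these pairs, some of which also share sequence. The 2 arms of a hairpin share a transcript as well, yet over 61 hairpins their log2 ratios did not go together (Pearson's r = -0.052). Sharing a transcript was therefore not enough to give similar ratios in these libraries.

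The share of reads not assigned to known miRNAs was 21.0% in the control and 25.4% in the ethanol library; the classes of RNA behind it were not analysed here.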
